A study of Homo sapiens with 4 samples.

How the data were processed

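The series comprises 4 samples of MCF7L cells, grouped by their titles into FOXA1 immunoprecipitates and inputs of parental cells treated with 4-hydroxytamoxifen and of tamoxifen-resistant cells grown in it. Peak lists were at hand for the 2 immunoprecipitates, and the 2 inputs were not analysed here. Per the labels' protocols, fixed chromatin was sonicated to fragments of 200 to 300 bp and immunoprecipitated with a FOXA1 antibody. A fraction without antibody served as input, and ThruPLEX-FD libraries were sequenced as 50 bp reads on an Illumina instrument. Per the submitters' processing notes, the genome build was hg19 and the tools included bcl2fastq 1.8.3 and TopHat2, with no role stated for either. The peak caller, its threshold and how the input entered the calling are not given in the sources used here. The resistant cells' length of exposure to the drug is likewise not given.

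Each deposited list holds 5 columns without a header, namely chromosome, start, end, peak name and score. The score in column 5 is the authors' peak caller's value for each peak, and its scale is not stated. Its lowest values were 2.08 in the parental and 2.01 in the resistant list, and its highest were 473 and 513. It was used only to rank and filter peaks within their own list, never to compare a peak between lists. Peak names mark each list as a single replicate, so peaks were called per library and not on pooled samples. Peaks were between 200 and 2459 bp wide and did not overlap within a list. The build was checked against a gene table of the assembly GRCh38, and 15 of 24 chromosomes had a peak beyond the last gene of that table, which argued against GRCh38 as the build of the peaks. The total number of reads per library is unknown, which leaves the sensitivity of each list unknown. Peak starts are given counting from 1.

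A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and private otherwise. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and their numbers equalled those of bedtools 2.31.1. In a test on 59856 simulated peaks with known classes, 100% were put in the right class. The simulated shared peaks were copies of parental peaks shifted by less than a peak width, so this outcome checks the code only. It does not measure how well overlap separates shared from private binding. A wide peak can meet more than 1 peak of the other list, which 60 parental and 130 resistant peaks did, so the numbers of shared peaks differ slightly between lists. Shares are given with 95% Wilson intervals from scipy 1.17.1, and the interval of a ratio of peak numbers was converted from that of the resistant share. These intervals cover counting error only. Neighbouring peaks are not independent and 1 list per condition carries no biological or technical spread, so no p-value between conditions is given. Chance overlap was estimated from 100 random circular shifts of the resistant peaks along each chromosome, up to the last peak end found there. Each list was also divided into score deciles, and peaks were counted by the position of their centre per chromosome, per 10 Mb and per 1 Mb. Figures were drawn with matplotlib 3.10.9.

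The main comparisons, the alternatives and the rule for naming items were fixed before the data were examined. The widths and scores of shared and private peaks, the distances to the other list and the stretches of consecutive 1 Mb bins were not in that plan. The rule named, for want of an annotation of the same build, the 10 bins of 1 Mb with the largest excess of resistant-private over parental-private peaks and the 10 with the largest excess the other way, with ties broken by the summed score of the private peaks. It also named the 3 highest-scoring peaks of each class, shared peaks being ranked in each list separately. Planned comparisons of promoter, exon and intron content, of transcription factor motifs and of peaks near genes in fixed lists were not made, since no hg19 sequence or annotation was used here. The alternatives tried were a reciprocal overlap of 50%, peak centres within 500 bp of each other, the higher-scoring 50% of each list, lists of equal length, autosomes and X only, and that 50% of each list against the whole other list.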

Results

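FOXA1 binding was profiled by chromatin immunoprecipitation and sequencing in MCF7L cells, a line of the estrogen receptor-positive MCF-7 breast cancer cells. FOXA1 is a forkhead pioneer factor that opens chromatin and through which the estrogen receptor reaches many of its enhancers. The parental cells had been given 4-hydroxytamoxifen, the active metabolite of tamoxifen, for 45 minutes, whereas the tamoxifen-resistant derivatives were grown in it. The series holds 4 samples, of which the 2 FOXA1 immunoprecipitates, 1 per condition, were analysed here as lists of called peaks. The 2 input samples were not analysed here. The number of reads behind each list is unknown, so the lists differ in cell state, in length of exposure to the drug and, to an unknown degree, in depth. With 1 list per condition the comparison has no replicate check, and no test between the conditions was possible. The 95% intervals given below are Wilson intervals that cover counting error only and treat peaks as independent.

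The first comparison asked how far FOXA1 occupied the same sites in parental and resistant cells. The resistant list was the longer, with 53275 peaks against 37358 in the parental list, a ratio of 1.43. It covered 18.6 Mb of the genome, against 12.4 Mb for the parental list. Of the parental peaks, 21578 overlapped a resistant peak by at least 1 bp, which was 57.8% (95% interval 57.3 to 58.3%). Of the resistant peaks, 21507 overlapped a parental peak, which was 40.4% (95% interval 40.0 to 40.8%). Resistant peaks moved at random along their chromosomes met only 1.23% ± 0.051 (SD over 100 shifts) of the parental peaks. The shifts ignored which sequence is mappable or open, so this is the overlap of peaks placed anywhere, a low mark to exceed. There remained 31768 peaks found only in the resistant list and 15780 found only in the parental list, a ratio of 2.01 (95% interval 1.98 to 2.05). The ratio depends by construction on the lengths of the lists, since nearly equal numbers of peaks are shared. When the resistant list was shortened to its 37358 highest-scoring peaks, 48.6% of parental peaks were shared, and 19321 resistant and 19218 parental peaks had no partner, numbers that equal lengths force to be nearly the same.

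Peaks found in both lists were the broader and higher-scoring ones within each list. In the parental list the median width was 330 bp for shared peaks and 278 bp for private peaks. In the resistant list the corresponding widths were 355 bp and 288 bp. The median score, the authors' own value for each peak and used only within a list, was 23.6 for shared and 12.4 for private parental peaks, and 28.7 for shared and 12.7 for private resistant peaks. Private peaks were not only weak ones, however. In the top score decile of the parental list, 535 of 3736 had no resistant partner, or 14.3% (95% interval 13.2 to 15.5%). In the top decile of the resistant list, 1247 of 5328 had no parental partner, or 23.4% (95% interval 22.3 to 24.6%). In the lowest decile the shares without a partner were 63.5% and 81.7%, respectively. Parental peaks were matched against the longer list and resistant peaks against the shorter, so list length enters the difference between the 2 lists. With the lists at equal length, 17.7% of the parental and 20.5% of the resistant top decile had no partner. Few of the strong private peaks lay beside a peak of the other list. Of those 535 parental peaks, 2.06% had a resistant peak centre within 1 kb, and of the 1247 resistant peaks 2.73% had a parental one. Private peaks overlap no peak of the other list by definition, and no share expected by chance was computed. These shares therefore say only that few were near misses of the overlap rule.

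**Figure D1:**
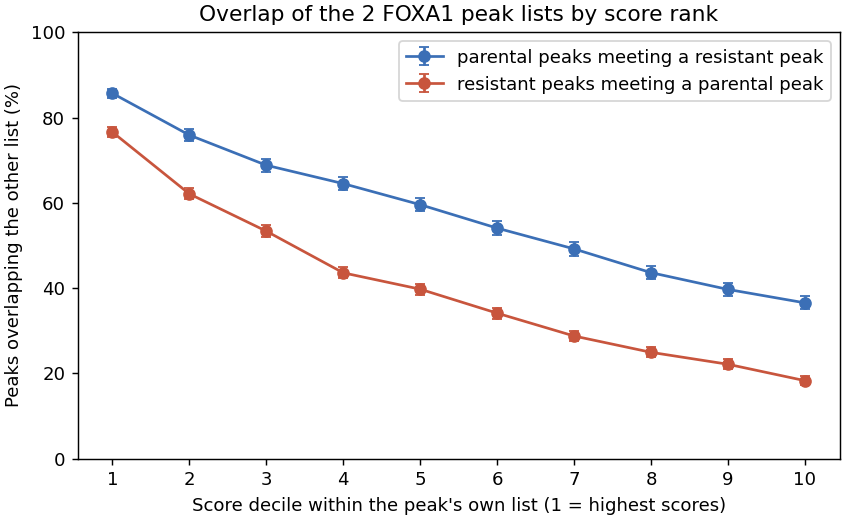
Share of peaks overlapping the other list by at least 1 bp (y axis, percent) against the score decile of the peak within its own list (x axis, 1 is the highest), for parental (blue) and resistant (red) peaks; bars are 95% Wilson intervals for counting error. The share fell from 85.7% to 36.5% for parental peaks and from 76.6% to 18.3% for resistant peaks.

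The sites with the highest scores illustrate both kinds of peak, in coordinates of the human genome build hg19. Among shared peaks, the highest in the parental list lay on chromosome 8 from 94080431 to 94081018, on chromosome 20 from 40278896 to 40279613 and on chromosome 1 from 117248533 to 117249280. The highest shared peaks in the resistant list lay on chromosome 2 from 121793517 to 121794370, on chromosome 10 from 110481447 to 110482291 and on chromosome 15 from 69759919 to 69760524. The highest-scoring peak of the whole parental list, on chromosome 17 from 61829923 to 61830568 with a score of 473, had no resistant partner, and the nearest resistant peak centre was 5.72 kb away. The next parental-private peaks were on chromosome 7 from 34275603 to 34276118, ranked 4 in its list, and on chromosome 2 from 154085533 to 154086162, ranked 29. Their nearest resistant peak centres were 70.2 and 62.6 kb away. The highest resistant-private peaks lay on chromosome 15 from 96101280 to 96101799, on chromosome 18 from 52403950 to 52404698 and on chromosome 4 from 108814993 to 108815441. They ranked 13, 51 and 97 among the 53275 resistant peaks, and their nearest parental peak centres were 71.3, 30.2 and 2.55 kb away. Genes and transcript features at these positions were not assigned here, because no hg19 annotation was used.

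The second comparison asked whether the difference between the lists was spread evenly over the genome. It was not. The resistant list held the larger number of peaks, with an interval above 1, on 20 of 23 chromosomes, but the ratio of resistant to parental peaks ranged from 1.01 on chromosomes 19 and X to 1.87 on chromosome 4. On chromosome 4 there were 3384 resistant and 1808 parental peaks, a ratio of 1.87 (95% interval 1.77 to 1.98). Chromosomes 13 and 2 followed, with ratios of 1.71 (95% interval 1.58 to 1.85) and 1.67 (95% interval 1.60 to 1.75). Chromosome 14, which carries the FOXA1 gene, had a ratio of 1.57 (95% interval 1.47 to 1.66). Chromosome X held 1039 resistant and 1029 parental peaks, chromosome 19 held 859 and 852, and chromosome 10 held 2116 and 2006. For 7 chromosomes the interval lay above the overall ratio of 1.43, and for another 7 it lay below. With the lists at equal length, 6 chromosomes had more resistant and 7 more parental peaks, by intervals that excluded 1. Chromosome 4 then had a ratio of 1.31 and chromosome X one of 0.644. Equal totals force ratios above 1 on some chromosomes to be met by ratios below 1 on others. The values at equal length therefore show the unevenness between chromosomes, and not a loss of peaks on any of them. Chromosome Y had 1 peak in each list and was left out of these counts.

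**Figure D2:**
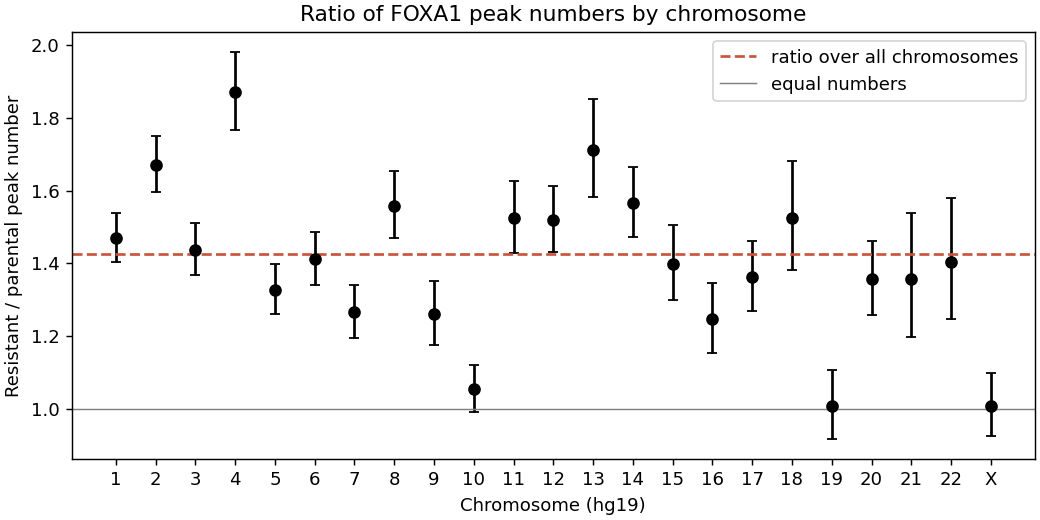
Number of resistant peaks divided by the number of parental peaks (y axis) for each hg19 chromosome (x axis); points are the 2 deposited lists compared, bars are 95% intervals for counting error, the dashed line is the overall ratio of 1.43 and the grey line marks equal numbers. Chromosome 4 stood highest at 1.87, and chromosomes 10, 19 and X lay near 1.

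At a finer scale, private peaks of one kind gathered in certain segments. Of 296 segments of 10 Mb with at least 30 private peaks, 76 had a resistant-private share with an interval wholly above the genome-wide share of 66.8%, and 78 had one wholly below it. The share ranged from 23.4% to 93.3% around a median of 66.9%. Against equal numbers of private peaks, which the longer resistant list makes an uneven mark, 226 segments lay above 50% and 8 below, by their intervals. It was highest on chromosome 5 from 20000001 to 30000000, where 112 resistant-private peaks stood against 8 parental-private ones. Chromosome 4 from 60000001 to 70000000 came next, with 123 against 9. On chromosome 2, the first 10 Mb held 211 resistant-private and 26 parental-private peaks. The share was lowest on chromosome X from 130000001 to 140000000, with 33 resistant-private and 108 parental-private peaks. Chromosome 19 from 50000001 to 60000000 held 31 and 62, and chromosome 20 from 30000001 to 40000000 held 62 and 121.

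Among bins of 1 Mb, 4 of the 10 with the largest excess of resistant-private peaks lay on chromosome 14 and 3 lay on chromosome 20. The largest excess was on chromosome 14 from 37 to 38 Mb, where 80 resistant-private peaks stood against 10 parental-private peaks and the lists held 101 and 31 peaks in all. The bins of chromosome 14 from 27 to 28 Mb and from 30 to 31 Mb had 40 and 38 resistant-private peaks and 0 parental-private peaks. The bin from 43 to 44 Mb had 40 against 2. On chromosome 20 the bins were 52 to 53 Mb, with 60 resistant-private and 16 parental-private peaks, 45 to 46 Mb, with 43 and 5, and 46 to 47 Mb, with 53 and 15. The remaining 3 were chromosome 12 from 65 to 66 Mb with 46 against 4, chromosome 2 from 46 to 47 Mb with 49 against 8, and chromosome 8 from 125 to 126 Mb with 51 against 14. With the lists at equal length the excess fell by more than 1.5 times in 5 of these bins. It went from 38 to 20 and from 38 to 16 on chromosome 20 from 45 to 46 Mb and from 46 to 47 Mb, from 42 to 23 on chromosome 12, from 41 to 27 on chromosome 2 and from 37 to 19 on chromosome 8. The 4 bins of chromosome 14 had excesses of 58, 33, 31 and 30 at equal length, against 70, 40, 38 and 38 in the deposited lists.

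Of the 10 bins with the largest excess of parental-private peaks, 4 lay on chromosome 10. Resistant-private minus parental-private peaks ranged from -17 to -13 in these bins and from 37 to 70 in the bins above, but from -23 to -14 and from 16 to 58 with the lists at equal length. Chromosome 10 from 114 to 115 Mb had 26 parental-private peaks against 9 resistant-private ones, the bin from 8 to 9 Mb had 19 against 4, the bin from 9 to 10 Mb had 14 against 0, and the first 1 Mb had 21 against 8. On chromosome 9 the bins from 137 to 138 Mb and from 135 to 136 Mb had 15 against 0 and 17 against 3. Chromosome X from 133 to 134 Mb had 18 against 2, and chromosome 7 from 108 to 109 Mb had 19 against 4. Chromosome 6 from 157 to 158 Mb had 16 against 1, and chromosome 3 from 106 to 107 Mb had 18 against 5. These 20 bins were chosen for the size of their excess, so their values are extremes of these 2 lists.

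**Figure D3:**
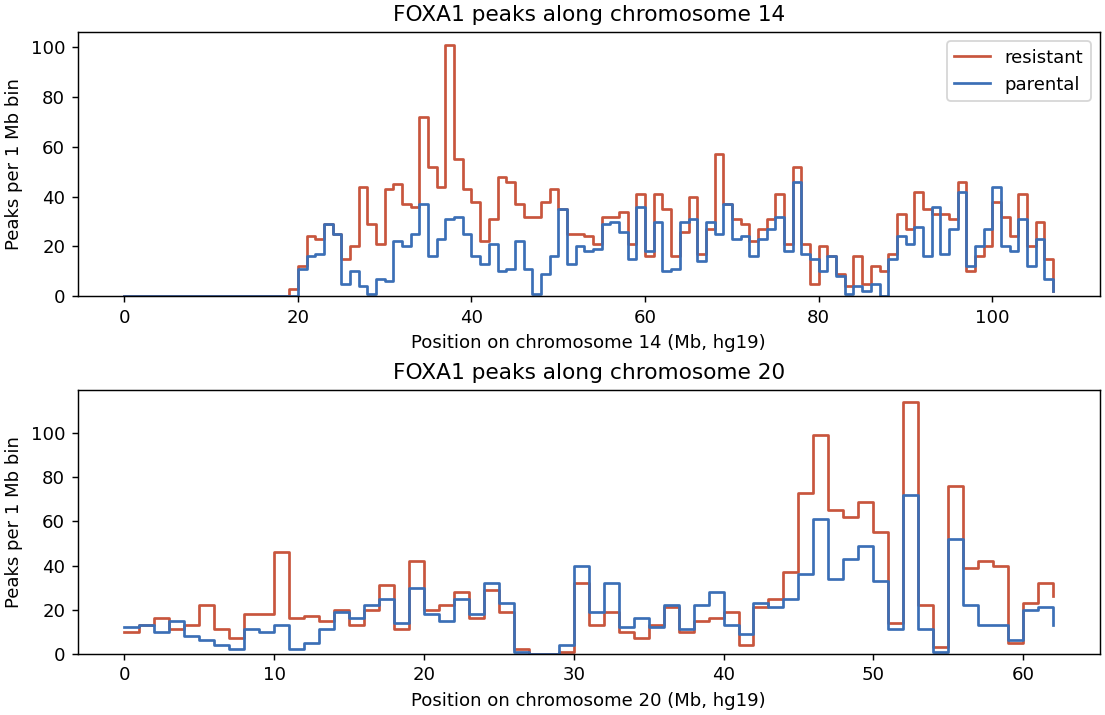
Peaks per 1 Mb bin (y axis) along chromosomes 14 and 20 (x axis, Mb in hg19) in the resistant (red) and parental (blue) lists. On chromosome 14 the bin from 37 to 38 Mb held 101 resistant and 31 parental peaks, and on chromosome 20 the bin from 52 to 53 Mb held 114 and 72.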

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

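No replicate could be left out, since each condition had 1 list, and the other settings listed beforehand for annotation, motifs and gene lists were not run for want of a sequence and annotation of the same build. With a reciprocal overlap of 50%, 52.9% of parental and 37.1% of resistant peaks were shared, the ratio of resistant-private to parental-private peaks was 1.90, and 19.5% and 32.5% of the top deciles were private. With centres within 500 bp, 40.9% of resistant peaks were shared. With the higher-scoring 50% of each list, 55.7% of parental and 39.0% of resistant peaks were shared, leaving 8278 and 16261 private peaks, a ratio of 1.96. The top deciles were then 17.2% and 28.2% private, and resistant-private peaks made up 45.1% of private peaks on chromosome X. With lists of equal length, 48.6% and 48.3% were shared, 19321 resistant peaks were private, the ratio was 1.01, which equal lengths fix near 1, and the top deciles were 17.7% and 20.5% private. The resistant-private share was then 62.2% on chromosome 4 and 31.7% on chromosome X, against 76.0% and 50.4% in the deposited lists. With that 50% of each list against the whole other list, 70.9% of parental and 55.1% of resistant peaks were shared, leaving 5437 and 11965 private peaks, a ratio of 2.20. In 5 of the 10 bins of 1 Mb named for a resistant-private excess, equal length lowered the excess by more than 1.5 times, to between 16 and 27 peaks. With the higher-scoring 50% of each list the 20 named bins ranged from -12 to 45. Restricting the lists to autosomes and X kept the 3 shares and ratios it applied to within their intervals and removed 1 private peak from each list. Fewer peaks entered the shortened lists, which by construction lowers their numbers of private peaks. The depth of the libraries, which limits how many sites each list can hold, is unknown.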

Other observations

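The grouping of neighbouring peaks, the limits of the chromosome 14 segment, the bins with each chromosome's mean taken out, the run of resistant-private peaks and the test of sparse binding were chosen only after results were seen; the other tests below had their bounds set beforehand. Dense groups of FOXA1 peaks, with neighbours at most 10 kb apart and at least 5 peaks, numbered 808 in the resistant and 248 in the parental list. With the lists at equal length the resistant list had 349 such groups and the parental list again 248. With a limit of 12.5 kb between neighbours the deposited lists had 1062 and 367 groups. The resistant group with the most peaks lay on chromosome 20 from 45916775 to 45990613, with 23 peaks against 14 parental peaks in the same interval. The parental list had its largest groups, of 12 peaks each, on chromosome 15 from 99387092 to 99425156, on chromosome 17 from 57914519 to 57952534 and on chromosome 20 from 52352204 to 52390950, where the resistant list held 16, 14 and 13 peaks. In the resistant list 82 groups, or 10.1% (95% interval 8.25 to 12.4%), held no parental peak. The largest of these was on chromosome 6 from 16711744 to 16737401 with 12 resistant peaks. In the parental list 10 groups, or 4.03% (95% interval 2.20 to 7.26%), held no resistant peak. The length of each list enters these shares, and with the lists at equal length they were 7.16% (95% interval 4.90 to 10.4%) of resistant and 5.24% (95% interval 3.09 to 8.76%) of parental groups, with intervals that overlapped. The largest parental ones in the deposited lists, with 6 peaks each, were on chromosome 10 from 19499897 to 19521701 and from 114515338 to 114539327, and on chromosome 12 from 96111695 to 96136627.

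The number of peaks also changed along chromosomes in long stretches, a comparison that was not planned beforehand. On chromosome 14 each of the 25 consecutive 1 Mb bins from 25 to 50 Mb held more resistant than parental peaks, 1024 against 394 in all, a ratio of 2.60. From 50 to 107 Mb the ratio was 1.26. Over 20 to 50 Mb it was 2.31 (95% interval 2.08 to 2.57), and it was 1.83 with lists of equal length and 2.69 with the higher-scoring 50% of each list. Chromosome 14 was not alone, and a list longer by a ratio of 1.43 gives some such stretches by itself. The first 49 bins of chromosome 2 held 1429 resistant and 686 parental peaks, and the 35 bins of chromosome 5 from 1 to 36 Mb held 718 and 273. In the other direction, 15 consecutive bins of chromosome X from 128 to 143 Mb held 103 resistant and 203 parental peaks.

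The first pattern weighed was the greater length of the resistant list. If the parental library were only the less sensitive, its strong peaks would nearly all have been found again in the resistant list. Of the higher-scoring 50% of the parental list, 29.1% (95% interval 28.5 to 29.8%) overlapped no resistant peak, above the 5% set beforehand. This argues against sensitivity as the only difference between the lists. Parental peaks that were not found again do not tell why the resistant list was longer. A difference in depth remains open for some or all of the extra resistant peaks, since the number of reads behind each list is unknown. Whether the resistant state, the longer exposure to the drug or ordinary variation between libraries contributed was not tested, since each condition had 1 library.

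The second pattern was the uneven ratio of peak numbers between chromosomes at equal list length. The mean chi-square between chromosomes was 13.2 times that between 1 Mb bins within chromosomes. In 10000 reassignments of the bins it was at most 3.0 times. This argues against one difference in depth or threshold that changes peak numbers by the same factor on every chromosome. The reassignments treated bins as exchangeable, although neighbouring bins were correlated, as given below. A common difference could still act unequally where chromosomes differ in their mix of strong and weak peaks, which was not compared. A spread of resistant peaks into regions of sparse binding predicts higher resistant-private ratios where shared peaks are few. Across 294 bins of 10 Mb, the log2 ratio of private peaks had a Spearman rho of -0.049 with the number of shared peaks. The 95% bootstrap interval of rho was -0.17 to 0.067 (permutation p = 0.4042, two-sided). The test cannot tell whether such a spread took place, because the interval holds both negative and positive values of rho. A negative rho, as the spread predicts, stays open down to -0.17, and stronger negative values lay outside the interval. Single bins of the deposited lists went both ways. The bin with the highest resistant-private share, on chromosome 5, had only 8 shared peaks. Chromosome 21 from 20000001 to 30000000 had only 4, but held 24 resistant-private against 32 parental-private peaks. The log2 ratios of neighbouring 10 Mb bins were correlated across 275 pairs, with a Pearson r of 0.40 (permutation p = 0.0001, one-sided, the smallest the 10000 shuffles can give). After each chromosome's mean was taken out, r fell to 0.20, against a 95th percentile of 0.020 in the shuffles. Taking out the means lowers r by itself, and the 95th percentile before that step was 0.096. Differences between whole chromosomes may have added to the 0.40, but the fall in r does not measure how much. Only the weaker r of 0.20 speaks for segments within chromosomes. A difference that runs over large segments, such as copy number, would give a correlation of this kind. A gain of part of chromosome 14 is a candidate explanation in the segment from 25 to 50 Mb, but the ratios did not single this segment out. Its ratio was 2.60, and that of chromosome 5 from 1 to 36 Mb was 2.63. In windows of 20 Mb, chromosome 4 from 20 to 40 Mb reached 2.58 and chromosome 14 from 30 to 50 Mb 2.44. Bins are not independent replicates, broad changes in chromatin would give the same correlation, a GC bias of either library was not tested, and neither input was analysed here, so copy number itself remains a hypothesis.

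The third pattern was that private peaks follow one another. In the order of all 69126 sites along the chromosomes, the longest run of consecutive parental-private peaks was 15, on chromosome 21 from 20090081 to 22749748, against a 95th percentile of 10 and a longest run of 17 in 10000 shuffles within chromosomes (permutation p = 0.0005, one-sided). The longest run of resistant-private peaks was 81, on chromosome 5 from 25488155 to 31386580, against a 95th percentile of 19 and a longest run of 29 in the shuffles. Loss of single parental peaks independently and with the same chance at every site of a chromosome is therefore argued against. The shuffles ignored score, although the private share rose from 14.3% in the top to 63.5% in the lowest parental decile. Independent loss with unequal chances along a chromosome stays open. Segments of altered copy number and domains of altered chromatin remain open and were not told apart.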
